A study of Mus musculus with 40 samples.

How the data were processed

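The series holds 40 bulk RNA sequencing libraries of mouse developing oligodendrocytes in 10 groups of 4: untreated and IFN-gamma cells at 1, 8, 24 and 48 h and thapsigargin cells at 1 and 8 h. Per the labels, oligodendrocyte progenitors were purified with antibody-coated plates from pup cortices, passaged, put into differentiation and treated, and total RNA was column-purified with DNase treatment and sequenced on an Illumina HiSeq instrument. The deposited gene table holds raw read counts, whole numbers for 39056 gene identifiers, of which 38872 matched a symbol in the reference annotation. The deposited isoform table holds estimated counts, which need not be whole, for 112588 transcripts. STAR, featureCounts, kallisto and edgeR are named per the submitters' processing notes, which give neither their versions nor their roles. The genome build, the annotation and the use of strand in counting are not given in the sources used here, and the GENCODE M21 reference was used for names only, so no coordinates are reported. Each group was taken from the labels, and every value column was matched to a sample by the library number in its name.

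Genes with low counts were removed with filterByExpr by group, which left 15135 genes. Counts were scaled by the trimmed mean of M values (TMM), and 1 model with a mean for each of the 10 groups was fitted to all 40 libraries with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest), leaving 30 residual degrees of freedom. Each treatment was compared with untreated cells of the same time, untreated cells of 8, 24 and 48 h with those of 1 h, and the treatments with each other, and differences of effects between times were tested as interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Log2 fold changes use a prior count of 0.125, and standard errors were taken as the fold change divided by the root of the F statistic. Levels are CPM on TMM-scaled library sizes, as the mean and SD over 4 libraries. A fold against a group with 0 reads is given as a lower bound, with 3 reads over the group as the floor, and such bounds cover counting error only.

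Named genes followed a rule set before the data were examined, as were the gene lists, the tests and most of the other settings tried. For each treatment comparison the rule takes the 6 largest rises and falls among called genes with a mean log2 CPM of at least 1 and no overlap between libraries of the groups, up to 4 called members of each list, and 23 genes named whatever their values, and some genes that it takes are not reported here. The untreated comparisons use its first and last parts. In the interactions and the direct comparison of treatments, examples were chosen from the list members after their values were seen. The 30 lists, written from general knowledge and not from these libraries, cover interferon-gamma signalling and transcription factors, GBP and IRG GTPases, type I interferon-stimulated genes, MHC class I antigen processing, constitutive 20S proteasome, MHC class II presentation, chemokines and cytokines, immune checkpoint, adhesion and death receptors, complement, NF-kappaB feedback, integrated stress response (ATF4 and CHOP targets), ATF6 and XBP1 chaperone and ERAD targets, apoptosis, immediate early genes, NRF2 oxidative stress targets, heat shock response, myelin and oligodendrocyte maturation, premyelinating oligodendrocyte, oligodendrocyte progenitor, oligodendrocyte lineage transcription factors, cholesterol biosynthesis, proliferation, disease-associated oligodendrocyte, astrocyte markers, microglia and macrophage markers, neuron markers, endothelial and mural markers, fibroblast and meningeal markers, mitochondrially encoded transcripts and ribosomal proteins. Lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation, with a block and with fry. Camera compares a list with the other genes, and its direction had the sign of the list's median for every list it called.

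The depth was 13165483 to 22651092 reads on genes per library, which limits genes of few reads. The model was tested on simulated counts with known changes. These were planted only in genes above a floor of expected reads, so the shares recovered do not cover genes of few reads. For IFN-gamma at 1 h (14695 genes) it recovered 70.1% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes with 2.79% false calls. For IFN-gamma at 8 h (14668 genes) the shares were 70.1, 89.6 and 98.5% with 6.01% false calls, and for thapsigargin at 1 h (14664 genes) 79.1, 91.04 and 96.97% with 4.30%.

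The other settings tried were size factors of the RLE method, DESeq2 1.42.0, no filter on low counts, a fit on only the groups compared, and a block for the lower and upper 20 library numbers. The labels do not call these ranges batches. Further ones took each range alone, the isoform table summed per gene and rounded to whole numbers (112029 transcripts matched, 38863 genes), and each library left out. A covariate for the level of the Y-linked genes and the removal of 7 ribosomal-RNA-like or repeat-derived features (AY036118, CT010467.1, Gm26917, Gm42418, Lars2, Gm10800, Gm10801) were added after seeing the data, and these features, Xist and the Y-linked genes were singled out after their values were seen. Overlaps between treatments were set beside simulated unchanged groups, since both use the same untreated libraries.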

Results

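Gene expression was measured by bulk RNA sequencing in developing oligodendrocytes of wild-type C57BL/6 mice, the glial cells that go on to form myelin. Progenitors had been immunopanned from pup cortices, expanded and left to begin differentiation before the plates were assigned at random to treatment, per the labels. Cells were untreated, given interferon-gamma (IFN-gamma, a cytokine of activated T cells) at 200 U/ml, or given thapsigargin, an inhibitor of the endoplasmic reticulum (ER) calcium pump used to provoke ER stress, at 200 uM as the labels state it. Untreated and IFN-gamma cells were collected at 1, 8, 24 and 48 h and thapsigargin cells at 1 and 8 h, with 4 libraries in each of the 10 groups and 40 in all. The libraries held between 13165483 and 22651092 reads on genes, and 15135 genes passed the filter on low counts and were tested. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of at least 6.04. The labels do not say whether the 4 replicates are separate cultures or animals. The p-values measure the spread between these libraries, pooled for each gene over all 10 groups, which may in part be technical. The spread of the 2 groups compared can differ from this pooled value.

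Libraries also differed in ways that the groups do not describe. The summed level of the Y-linked genes Kdm5d, Eif2s3y and Uty was between 103 and 299 CPM (counts scaled to the TMM-adjusted library size) in all 16 untreated libraries, whose level of Xist, the transcript of the inactive X chromosome, lay between 0 and 183 CPM. The Y-linked level was under 10 CPM in 8 of the 16 IFN-gamma libraries, 2 in each group, and there Xist was between 319.5 and 718 CPM. In the other 8 IFN-gamma libraries the Y-linked level was between 196 and 255 CPM and Xist at most 11.1 CPM. Thapsigargin replicate 2 had a Y-linked level of 20.6 CPM at 1 h and 14.6 CPM at 8 h, with Xist at 423 and 729 CPM. IFN-gamma 1 h replicate 2 had 28.3% of its reads on ribosomal-RNA-like features, against 0.696 to 3.58% in the other 3 libraries of its group. The labels number the libraries, and the lower and the upper 20 numbers each hold 2 libraries of every group.

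**Figure D1:**
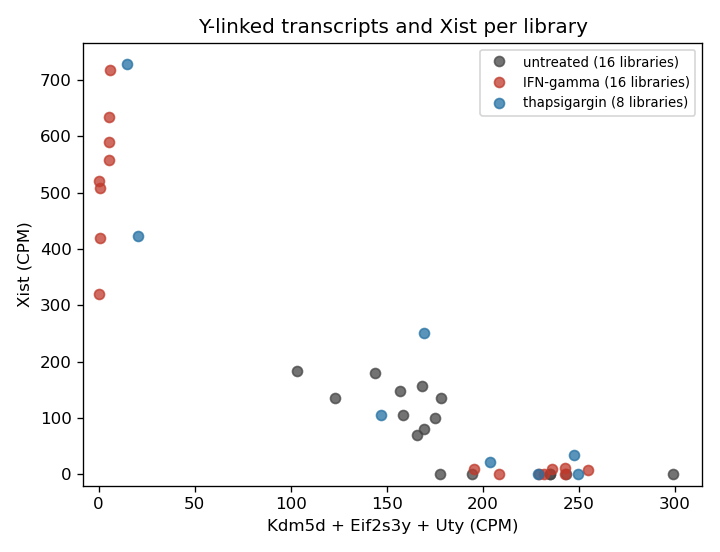
Summed CPM of 3 Y-linked genes (x axis) against CPM of Xist (y axis), 1 point per library, in 16 untreated, 16 IFN-gamma and 8 thapsigargin libraries. The 8 IFN-gamma libraries at the left have Y-linked levels between 0.469 and 6.08 CPM and Xist at or above 319.5 CPM, and every untreated library lies at or above 103 CPM of the Y-linked genes.

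The untreated series gives the background of change with time in culture against which each treatment was set. Between 1 and 48 h myelin genes of untreated cells rose: Mbp (myelin basic protein) rose from 46.7 ± 14.8 to 1802 ± 1115 CPM (SD, n = 4 each), a log2 fold change of 5.27 ± 0.68 (SE; adjusted p = 5.77e-08), and Mog rose by 5.35 ± 0.62 on the log2 scale. The premyelinating marker Enpp6 rose by 5.83 ± 0.74, together with St18, Tmem163 and the dopa decarboxylase gene Ddc (5.49 ± 0.55), and Myrf, a transcription factor of myelination, rose by 2.56 ± 0.31. The progenitor receptor Pdgfra fell by 1.07 ± 0.17 and the immediate early genes Klf4, Egr2 and Egr1 changed by -5.11 ± 0.39, -4.26 ± 0.31 and -3.57 ± 0.39.

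Genes are counted below as rising or falling at an adjusted p under 0.05 over all genes tested, and a count adjusted over the list alone is given where it differs. For a treatment, rising or falling means higher or lower than in untreated cells of the same time, not a change between times. For lists that camera called, its p, adjusted over the 30 lists, is given, and also the adjusted p with an estimated correlation where that ended the call. In the comparisons with untreated cells of the same time, or of untreated cells between times, a list without a camera p was not called by it. Camera was not run on the interactions or on the direct comparison of treatments, where only counts of genes are given. By list, 20 of 23 measured myelin and maturation genes rose (camera adjusted p = 6.85e-07, adjusted p = 0.688 with an estimated correlation). So did 13 of 13 premyelinating genes (camera adjusted p = 6.85e-07, adjusted p = 0.688 with an estimated correlation). Proliferation genes fell in 25 of 25 (camera adjusted p = 5.80e-12, adjusted p = 0.688 with an estimated correlation) and immediate early genes in 19 of 23 (camera adjusted p = 1.44e-07, adjusted p = 0.395 with an estimated correlation). Ribosomal protein genes fell in 26 of 26 (camera adjusted p = 2.06e-07, adjusted p = 0.731 with an estimated correlation). Of the integrated stress response list, which holds targets of the transcription factors ATF4 and CHOP, 19 of 35 fell (camera adjusted p = 0.00392, adjusted p = 0.767 with an estimated correlation). Trib3 changed by -2.52 ± 0.50. In all, 9436 genes changed from 1 to 48 h (4828 higher, 4608 lower). The count was 4282 from 1 to 24 h (2103 and 2179) and 1049 from 1 to 8 h (722 and 327), by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Cholesterol biosynthesis genes had risen in 11 of 24 by 8 h (19 adjusted over the list alone, camera adjusted p = 1.34e-11, adjusted p = 0.471 with an estimated correlation). Premyelinating genes had risen in 12 of 13 by 24 h (camera adjusted p = 2.34e-07, adjusted p = 0.553 with an estimated correlation). Immediate early genes had fallen in 14 of 23 by 8 h (16 adjusted over the list alone, camera adjusted p = 8.87e-12, adjusted p = 0.0653 with an estimated correlation). Without untreated 1 h replicate 1 or untreated 8 h replicate 4 immediate early genes fell in 9 by 8 h, and without untreated 8 h replicate 1 or 2 or untreated 1 h replicate 3 or 4 cholesterol genes rose in 7. The 8 h count is 538 without untreated 8 h replicate 4, 588 and 615 without untreated 1 h replicates 1 and 2, and within the lower and the upper 20 library numbers 125 and 182. With only the 2 groups compared in the fit it is 1913. Without untreated 24 h replicate 4 and in the lower 20 numbers the 24 h count is 2314 and 430. With the isoform table summed per gene 88.03% of the genes called at 8 h and 64.4% of the 2497 called at 24 h were higher, against 68.8% and 49.1%.

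The IFN-gamma comparisons ask how the transcriptome of treated cells departs from that of untreated cells of the same age. After 1 h transcription factors and GTPases of interferon signalling were among the genes that had risen. Irf1 (ENSMUSG00000018899.16), a transcription factor of the interferon response, rose from 25.5 ± 1.17 to 632 ± 182 CPM (SD, n = 4 each), a log2 fold change of 4.63 ± 0.13 (SE; adjusted p = 1.70e-24). Irf8 rose by 4.52 ± 0.21, the feedback inhibitor Socs1 by 3.24 ± 0.41 and Irf9 by 2.50 ± 0.12. The immunity-related GTPases Irgm2 and Igtp rose 176-fold and 168-fold, and the non-coding transcript 9330175E14Rik 44.99-fold. B2m was at 28.2 ± 7.67 CPM against 22.6 ± 2.72 and H2-K1 at 7.51 ± 2.61 against 7.46 ± 1.99, and neither passed the test. The peptide transporter gene Tap1 rose by 1.32 ± 0.15.

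Of the interferon-gamma signalling list 11 of 17 measured genes rose (12 adjusted over the list alone, camera adjusted p = 1.67e-45). Of the GBP and IRG GTPases 12 of 19 rose (camera adjusted p = 4.52e-44). Type I interferon-stimulated genes rose in 5 of 29 (camera adjusted p = 5.70e-06, adjusted p = 0.113 with an estimated correlation), led by Parp14 (2.72 ± 0.44), Rtp4 (2.44 ± 0.30) and Trim21 (2.33 ± 0.15). The MHC class I list rose in 5 of 20 (camera adjusted p = 7.05e-05, adjusted p = 0.113 with an estimated correlation). Its risers included Psmb9 (3.08 ± 0.19), Nlrc5 (2.67 ± 0.28) and Tap1 (1.32 ± 0.15), which encode an immunoproteasome subunit, the class I transactivator and a peptide transporter. The chemokine gene Cxcl1 (3.30 ± 0.52) and the cytokine gene Csf1 (1.34 ± 0.22) rose, in a list that rose in 2 of 9 (camera adjusted p = 0.00241, adjusted p = 0.0614 with an estimated correlation). Cd274 (3.83 ± 0.42) and Icam1 (3.49 ± 0.44), which encode a checkpoint ligand and an adhesion molecule, rose as well. Their list rose in 2 of 11 (3 adjusted over the list alone, camera adjusted p = 0.0156, adjusted p = 0.113 with an estimated correlation). The complement inhibitor gene Serping1 (3.93 ± 0.43) rose. Complement genes rose in 1 of 6 (2 adjusted over the list alone, camera adjusted p = 0.0412, adjusted p = 0.408 with an estimated correlation). Serpina3f (6.24 ± 0.44) and Serpina3i (1.93 ± 0.15) are examples from the disease-associated oligodendrocyte list, which rose in 2 of 14 (3 adjusted over the list alone, camera adjusted p = 3.50e-05). The genes that fell included Nr4a1 (-0.78 ± 0.15), Klf15 (-0.62 ± 0.12) and Ddit4 (-0.54 ± 0.11). The ribosomal protein list had a median log2 fold change of -0.13 (camera adjusted p = 2.27e-04, adjusted p = 0.614 with an estimated correlation). That of the 20S proteasome list was -0.10 (camera adjusted p = 0.00458, adjusted p = 0.614 with an estimated correlation), and that of the lineage transcription factors -0.22 (camera adjusted p = 0.0114, adjusted p = 0.113 with an estimated correlation).

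In all, 195 genes differed at 1 h (163 higher, 32 lower; edgeR quasi-likelihood test, adjusted p under 0.05), and 90 of them by at least 2-fold. Of the genes that rose, 141 were also higher at 8 h, where 21.3 would be shared by independent lists of those lengths. Without IFN-gamma 1 h replicate 3, MHC class I genes rose in 3. Without replicate 2, the library rich in ribosomal-RNA-like reads, 184 genes passed. In the lower 20 library numbers alone 80 genes passed, and with the isoform table summed per gene 94.4% of the called genes were higher, against 83.6%.

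**Figure D2:**
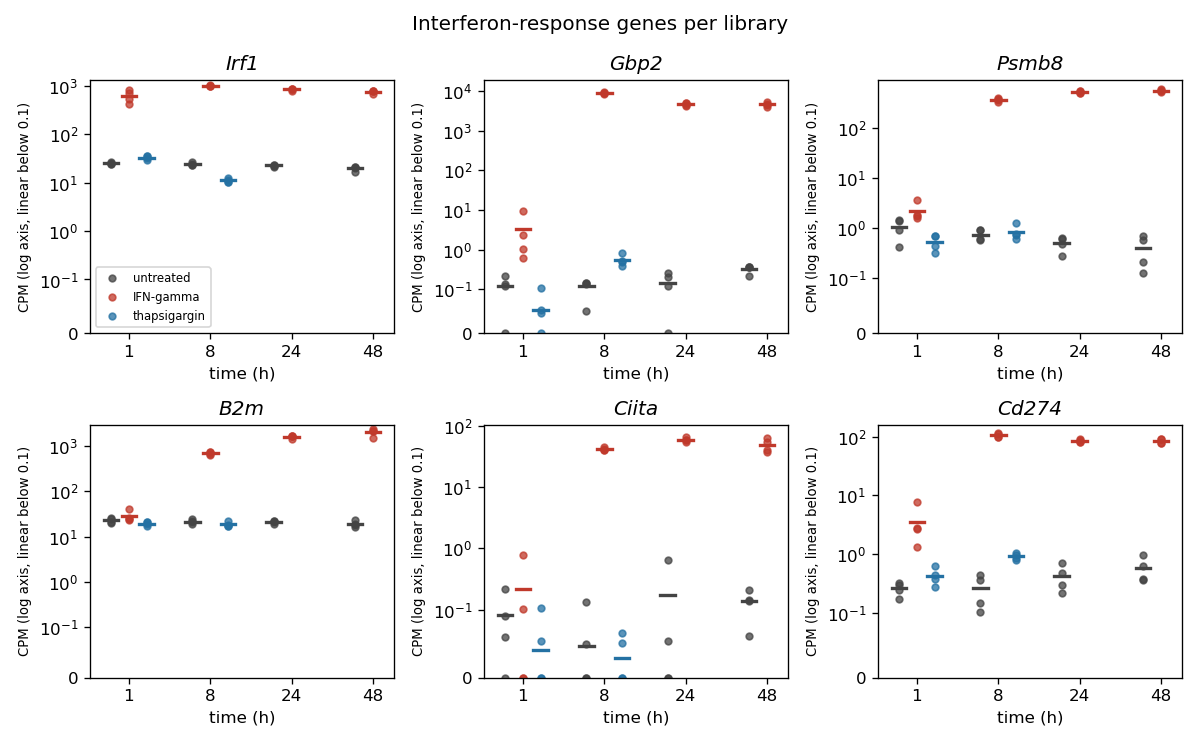
CPM of Irf1, Gbp2, Psmb8, B2m, Ciita and Cd274 (y axes, logarithmic above 0.1 and linear below) by time in h (x axes), 1 point per library and a bar at the mean of 4 libraries, for untreated, IFN-gamma and thapsigargin cells. Irf1 lies between 427 and 834 CPM in the IFN-gamma libraries of 1 h, and B2m has a mean of 28.2 CPM in them and of 685 CPM at 8 h.

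By 8 h antigen presentation genes had risen, and several genes of the oligodendrocyte lineage had fallen. Gbp2 (ENSMUSG00000028270.12), a guanylate-binding GTPase of cell-autonomous immunity, went from 0.118 ± 0.0459 to 8964 ± 475 CPM and was among the most abundant induced transcripts, with Iigp1 at 2458 ± 76.04 CPM. Tgtp2 and Ifi47 had 0 reads in all 4 untreated libraries and were at least 19987-fold and 14741-fold higher, taking 3 reads over the untreated group as the floor. Irf1 reached 1018 ± 31.7 CPM. B2m (ENSMUSG00000060802.8), the light chain of MHC class I, rose from 21.4 ± 2.19 to 685 ± 60.2 CPM (SD, n = 4 each), a log2 fold change of 4.99 ± 0.16 (SE; adjusted p = 2.47e-24). The immunoproteasome subunit Psmb8 rose by 8.91 ± 0.25 and the class II transactivator Ciita by 9.35 ± 0.49. The progenitor receptor Pdgfra (ENSMUSG00000029231.15) fell from 2648 ± 48.8 to 1441 ± 70.05 CPM (SD, n = 4 each), a log2 fold change of -0.88 ± 0.17 (SE; adjusted p = 1.46e-04). Myrf changed by -1.14 ± 0.30 and the premyelinating gene Gpr17 by -2.03 ± 0.36.

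All 19 GBP and IRG GTPases rose (camera adjusted p = 9.93e-57). All 20 MHC class I genes rose (camera adjusted p = 8.58e-55), with H2-T23 at 8.62 ± 0.27, Nlrc5 at 8.26 ± 0.32 and H2-K1 at 4.27 ± 0.22. The 7 MHC class II genes all rose (camera adjusted p = 9.31e-14). Type I interferon-stimulated genes rose in 28 of 29 (camera adjusted p = 2.63e-51), among them Parp14 (11.03 ± 0.40) and Ifit1 (11.06 ± 0.35), and Isg15 was at least 682-fold higher. Interferon-gamma signalling genes rose in 15 and fell in 2 of 17 (camera adjusted p = 2.09e-25). Chemokines and cytokines rose in 7 of 9 (9 adjusted over the list alone, camera adjusted p = 6.31e-10), with Cxcl10 at least 173-fold higher. Checkpoint, adhesion and death receptor genes rose in 8 of 11 (9 adjusted over the list alone, camera adjusted p = 2.76e-10), with Cd274 (8.56 ± 0.34). Complement genes rose in 4 of 6 (5 adjusted over the list alone, camera adjusted p = 2.30e-08), with Serping1 (10.01 ± 0.31) and C4b (3.20 ± 0.20). In the apoptosis list 12 of 21 rose (13 adjusted over the list alone, camera adjusted p = 3.58e-07), led by the inflammatory caspase genes Casp1 (7.54 ± 0.36), Casp12 (7.36 ± 0.21) and Casp4 (5.22 ± 0.25). The disease-associated oligodendrocyte list rose in 8 and fell in 4 of 14 (camera adjusted p = 1.25e-05). It shares B2m, H2-D1 and C4b with the preceding lists.

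Progenitor genes rose in 1 and fell in 10 of 18 (camera adjusted p = 9.92e-04, adjusted p = 0.12 with an estimated correlation), with falls of C1ql1 (-1.90 ± 0.25), Matn4 (-1.60 ± 0.40) and Xylt1 (-1.11 ± 0.16). Premyelinating genes rose in 1 and fell in 6 of 13 (camera adjusted p = 0.0201, adjusted p = 0.738 with an estimated correlation), with falls of Kif19a (-2.33 ± 0.59) and Neu4 (-1.95 ± 0.42). Myelin genes rose in 1 and fell in 5 of 23 (camera adjusted p = 0.0313, adjusted p = 0.804 with an estimated correlation), with a fall of Gal3st1 (-1.18 ± 0.22). Among the largest falls were Timp4 (-3.02 ± 0.19), Pnlip (-2.99 ± 0.37), Gpr37 (-2.99 ± 0.38) and Pcdh8 (-2.52 ± 0.25). Of the stress genes, Hspa5 was at 676 ± 16.4 CPM against 626 ± 46.01 and did not pass. Integrated stress response genes rose in 7 and fell in 2 of 35 (7 and 3 adjusted over the list alone), the largest rises being Atf3 (4.31 ± 0.38), Wars (2.87 ± 0.12) and Trib3 (2.23 ± 0.38). Trib3 stood at only 4.42 ± 0.805 CPM against 0.92 ± 0.196 in untreated cells, which had held 2.18 CPM at 1 h. In IFN-gamma cells it had been at 3.65 CPM at 1 h. The chaperone and ER-associated degradation list rose in 2 of 33 (1 adjusted over the list alone). Markers of other cell types moved in both directions. The neuron list rose in 3 of 9 (camera adjusted p = 0.0336), with Tubb3 (2.63 ± 0.14), Syt1 (1.12 ± 0.19) and Nefm (0.85 ± 0.17). The endothelial and mural gene Acta2 (5.05 ± 0.31) and the fibroblast gene Lum (4.88 ± 0.39) rose from 0.259 and 0.162 CPM. The astrocyte list rose in 1 and fell in 2 of 10.

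At 8 h 3811 genes differed (1977 higher, 1834 lower; edgeR quasi-likelihood test), 1055 of them by at least 2-fold. With the Y-linked level of each library as a covariate 3858 genes passed. Myelin genes fell in 3 without IFN-gamma 8 h replicate 1 or 2 or untreated 8 h replicate 4, and disease-associated genes in 2 without untreated 8 h replicate 1 or 2. The upper 20 library numbers alone gave 2456 genes.

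After 24 h antigen presentation genes were among the most abundant that rose, and some myelin genes were lower than in untreated cells. H2-K1 rose from 5.54 ± 1.40 to 1269.5 ± 38.7 CPM (SD, n = 4 each), a log2 fold change of 7.84 ± 0.26 (SE; adjusted p = 6.40e-24). B2m stood at 1593 ± 134 and H2-D1 at 1356 ± 42.9 CPM, and the class II genes H2-Aa, H2-Eb1 and Cd74 rose by 8.91 ± 0.36, 8.68 ± 0.30 and 7.00 ± 0.42. Gbp2 was at 4696 ± 368 CPM and Irf1 at 859.6 ± 46.9. Mbp changed by -1.70 ± 0.59, Enpp6 by -2.93 ± 0.65 and the secreted factor Bmp4 by -3.44 ± 0.56.

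All 19 GTPases (camera adjusted p = 4.93e-63), 20 MHC class I genes (camera adjusted p = 7.07e-71) and 7 MHC class II genes (camera adjusted p = 8.87e-22) rose again. So did 28 of 29 type I interferon-stimulated genes (camera adjusted p = 1.62e-57). Signalling genes rose in 15 and fell in 1 of 17 (camera adjusted p = 2.77e-25). Chemokines and cytokines rose in 7 of 9 (camera adjusted p = 6.17e-07). Checkpoint and death receptor genes rose in 8 of 11 (9 adjusted over the list alone, camera adjusted p = 9.39e-09), with Fas (2.63 ± 0.18) and Lgals9 (6.31 ± 0.39). Apoptosis genes rose in 8 of 21 (camera adjusted p = 5.30e-06). Complement genes rose in 4 and fell in 1 of 6 (5 and 1 adjusted over the list alone, camera adjusted p = 8.77e-08). Disease-associated genes rose in 6 and fell in 2 of 14 (camera adjusted p = 9.90e-05). Myelin genes fell in 11 of 23 (13 adjusted over the list alone, camera adjusted p = 1.66e-04, adjusted p = 0.471 with an estimated correlation), with Mog (-2.77 ± 0.65) and Opalin (-2.61 ± 0.45). Premyelinating genes rose in 1 and fell in 9 of 13 (1 and 11 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.471 with an estimated correlation). Progenitor genes rose in 1 and fell in 6 of 18 (1 and 10 adjusted over the list alone, camera adjusted p = 0.00491, adjusted p = 0.234 with an estimated correlation). Integrated stress response genes rose in 16 and fell in 1 of 35 (18 and 1 adjusted over the list alone, camera adjusted p = 0.00212, adjusted p = 0.471 with an estimated correlation). In untreated cells 14 genes of this list were lower at 24 h than at 1 h, or 9 without untreated 24 h replicate 4. Atf4 went from 174 to 133 CPM in untreated cells, against 163 and 167 CPM in IFN-gamma cells. Part of the difference at 24 h can therefore lie in the untreated cells. Trib3 stood at only 5.42 ± 3.25 CPM, and 1 library, replicate 1, held 10.3 CPM of it against 3.70 to 3.94 in the other 3. Proliferation genes rose in 1 of 25, Top2a (0.72 ± 0.20) being that gene (camera adjusted p = 0.0255, adjusted p = 0.789 with an estimated correlation). The fibroblast gene Lum (4.48 ± 0.33) and the neuron genes Tubb3 (1.79 ± 0.13) and Syt1 (0.97 ± 0.19) rose, while Acsbg1 (-0.58 ± 0.16) of the astrocyte list fell.

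At 24 h 3493 genes differed (1908 higher, 1585 lower; edgeR quasi-likelihood test), 1300 of those higher and 841 of those lower having been so at 8 h, against 249 and 192 for independent lists. The lower 20 library numbers alone gave 1526 genes. Untreated 24 h replicate 4 held 325 CPM of Mbp against 89.8 to 120.4 in the other 3. Without it 5 myelin and 3 premyelinating genes fell, the calls of Mbp (-1.06), Mog (-1.80) and Top2a (0.56) end, and Enpp6 (-1.95) and Bmp4 (-2.76) still pass. Without IFN-gamma 24 h replicate 1, premyelinating genes fell in 5 and integrated stress response genes rose in 7, and the latter rose in 10 without untreated 24 h replicate 2. The call of Mbp also ends without IFN-gamma 24 h replicate 1 (-1.48), 2 (-1.60) or 3 (-1.77).

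At 48 h most measured myelin genes were lower in IFN-gamma cells than in untreated ones. Mbp (ENSMUSG00000041607.16) fell from 1802 ± 1115 to 236 ± 159 CPM (SD, n = 4 each), a log2 fold change of -2.93 ± 0.61 (SE; adjusted p = 2.41e-04). Mog changed by -2.29 ± 0.49, Opalin by -3.11 ± 0.37 and Myrf by -0.89 ± 0.29. Cell-cycle genes were higher, Top2a rising by 1.00 ± 0.20 and Mcm6 by 0.93 ± 0.21, as did the lineage factors Sox9 (1.82 ± 0.39) and Olig1 (0.83 ± 0.17). Pdgfra did not pass, at 1259 ± 386 against 1116 ± 497 CPM. Interferon genes were higher as at 24 h. B2m was at 2034 ± 349 CPM, H2-K1 at 1533 ± 179.8, Psmb8 at 570.3 ± 36.2 and Gbp2 at 4614 ± 648, and Cd74, the class II invariant chain, at 17.7 ± 2.53.

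Myelin genes fell in 18 of 23 (21 adjusted over the list alone, camera adjusted p = 1.63e-06, adjusted p = 0.334 with an estimated correlation). Premyelinating genes fell in 9 of 13 (10 adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.527 with an estimated correlation), with Enpp6 (-1.94 ± 0.61), Kif19a (-1.89 ± 0.44) and Cnksr3 (-1.77 ± 0.37). Progenitor genes rose in 2 and fell in 7 of 18 (3 and 9 adjusted over the list alone), Ptprz1 (0.90 ± 0.12) and Id4 (-1.41 ± 0.28) being examples of each. Proliferation genes rose in 19 of 25 (22 adjusted over the list alone, camera adjusted p = 3.62e-04, adjusted p = 0.619 with an estimated correlation). Ribosomal protein genes rose in 9 of 26 (camera adjusted p = 8.97e-04, adjusted p = 0.619 with an estimated correlation). Integrated stress response genes rose in 10 and fell in 3 of 35 (camera adjusted p = 0.0448, adjusted p = 0.619 with an estimated correlation). Genes of this list had also fallen in untreated cells from 1 to 48 h. Cholesterol biosynthesis genes fell in 7 of 24 (camera adjusted p = 0.0146, adjusted p = 0.75 with an estimated correlation), with Hmgcs1 (-0.61 ± 0.17). Among the largest falls were Ddc (-3.91 ± 0.49), Gng4 (-3.81 ± 0.51), Plch2 (-3.67 ± 0.51), Elmod1 (-3.61 ± 0.43) and Fhl2 (-3.57 ± 0.33). Of the immune lists, GTPases rose in 19 of 19 (camera adjusted p = 4.46e-49), MHC class I in 20 of 20 (camera adjusted p = 7.47e-57) and MHC class II in 7 of 7 (camera adjusted p = 3.20e-17). Type I interferon-stimulated genes rose in 27 of 29 (28 adjusted over the list alone, camera adjusted p = 8.63e-48), chemokines and cytokines in 7 of 9 (camera adjusted p = 1.63e-06). Checkpoint and death receptor genes rose in 10 of 11 (camera adjusted p = 2.16e-08) and complement genes in 5 of 6 (camera adjusted p = 1.79e-07). Signalling genes rose in 15 and fell in 1 of 17 (camera adjusted p = 1.56e-19). Apoptosis genes rose in 11 and fell in 2 of 21 (12 and 2 adjusted over the list alone, camera adjusted p = 1.63e-06). Disease-associated genes rose in 6 and fell in 2 of 14 (7 and 2 adjusted over the list alone, camera adjusted p = 2.27e-05). NF-kappaB feedback genes rose in 5 and fell in 3 of 12, with Tnfaip3 (3.18 ± 0.25) and Bcl3 (0.99 ± 0.11) against Relb (-0.64 ± 0.16). NRF2 targets rose in 3 and fell in 1 of 11 (4 and 2 adjusted over the list alone), with Txnrd1 (0.55 ± 0.08) among those higher. Astrocyte markers rose in 2 and fell in 5 of 10, with Fgfr3 (-1.80 ± 0.18) and Aqp4 (-1.17 ± 0.33). The fibroblast list rose in 2 and fell in 1 of 3, with Igf2 (1.95 ± 0.37) and Lum (6.48 ± 0.42) against Postn (-2.78 ± 0.53). The endothelial and mural list rose in 2 and fell in 1 of 7. The neuron list rose in 3 of 9, with a median log2 fold change of 0.07. The 3 measured microglia and macrophage markers had a median log2 fold change of -0.11 (camera adjusted p = 0.89) and the 11 mitochondrially encoded transcripts of -0.03 (camera adjusted p = 0.89).

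At 48 h 5570 genes differed (2554 higher, 3016 lower; edgeR quasi-likelihood test), and 1055 genes were higher and 600 lower at all of 8, 24 and 48 h. Untreated 48 h replicate 2 stood apart, with 255 CPM of Mbp against 1731 CPM or more in the other 3, and so did IFN-gamma 48 h replicate 1, with 45.2 CPM against 193 to 425. Without IFN-gamma 48 h replicate 1, 4135 genes passed, proliferation genes rose in 2 and integrated stress response genes in 6, the call of Myrf (-0.59) ends, and Mbp (-2.58), Top2a (0.61) and Mcm6 (0.53) still pass. Without untreated 48 h replicate 3, Myrf (-0.79) does not pass and proliferation genes rose in 10, and without untreated 48 h replicate 1 in 12. Cholesterol genes fell in 3 without either replicate 1 and in 14 without untreated 48 h replicate 2. Ribosomal protein genes rose in 3 without untreated 48 h replicate 3 or 4, and in up to 20, without untreated 48 h replicate 2. Progenitor genes fell in 4 without untreated 48 h replicate 2 or IFN-gamma 48 h replicate 3 or 4; without the former Sox9 is at 2.71. With only the untreated and IFN-gamma libraries of 48 h in the fit 2041 genes passed, and the lower 20 library numbers gave 3039.

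**Figure D3:**
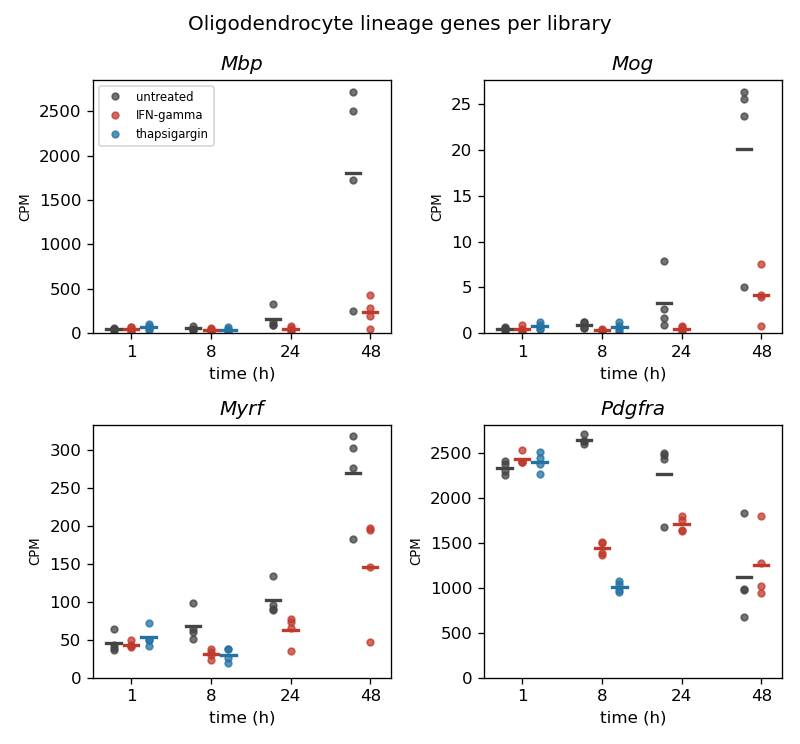
CPM of Mbp, Mog, Myrf and Pdgfra (y axes, linear, from 0) by time in h (x axes), 1 point per library and a bar at the mean of 4 libraries, for untreated, IFN-gamma and thapsigargin cells. Untreated Mbp climbs from a mean of 46.7 CPM at 1 h to 1802 CPM at 48 h, with replicate 2 low, and the mean of IFN-gamma cells at 48 h is 236 CPM.

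Whether the IFN-gamma effect itself changed with time was tested as a difference of effects. From 1 to 8 h the effect moved upward for 20 of 20 MHC class I genes, 18 of 19 GTPases and 26 of 29 type I interferon-stimulated genes, for instance by 4.68 ± 0.20 for B2m. Of the progenitor genes 5 of 18 moved downward and 1 upward, with Pdgfra at -0.94 ± 0.24. From 8 to 48 h it moved upward for 12 of 20 MHC class I genes and 11 of 25 proliferation genes and downward for 2 MHC class I genes, Nlrc5 (-1.82 ± 0.38) and Tapbp (-0.50 ± 0.14), and for 6 of 23 myelin genes. GTPases, which had moved upward before, now moved downward in 3 of 19, Gbp11 (-4.49 ± 0.96), Gbp6 (-3.94 ± 0.50) and Gbp9 (-1.62 ± 0.51), with a list median of -1.49, and signalling genes in 2 of 17, Jak1 (-0.52 ± 0.08) and Stat3 (-0.33 ± 0.06). At 8 h 2 GTPases had 0 reads in a group and Gbp2 was at 0.118 CPM in untreated cells. The GTPase median can therefore depend on few untreated reads. Progenitor genes now moved upward in 7 of 18 and downward in 2, with Pdgfra (1.05 ± 0.24) and Cspg4 (1.17 ± 0.26) upward. Pdgfra did not recover in IFN-gamma cells, with means of 1441 CPM at 8 h and 1259 CPM at 48 h. Its upward move came from untreated cells, which went from 2648 to 1116 CPM. The difference was 3.95 ± 0.30 for H2-K1 and 1.16 ± 0.29 for Mcm6, the latter 0.74 without IFN-gamma 48 h replicate 1. The call of Gbp9 ends without untreated 8 h replicate 1 (-1.29) or untreated 48 h replicate 2 (-1.47) or 3 (-1.55). With single libraries left out the proliferation genes moving upward were between 1 (without IFN-gamma 48 h replicate 1) and 24 (without untreated 48 h replicate 2), and the myelin genes moving downward were 3 without IFN-gamma 48 h replicate 1, untreated 8 h replicate 3 or untreated 48 h replicate 3 or 4. In all, 1874 genes differed in effect between 8 and 1 h (1119 upward, 755 downward) and 2577 between 48 and 8 h (1089 and 1488; edgeR quasi-likelihood test). The second count is 917 when only the 4 groups compared are fitted, 86 in the lower 20 library numbers, 1490 with the isoform table, and 4297 and 1689 without untreated 48 h replicates 2 and 3. The first is 839 and 1031 within the lower and the upper 20 numbers.

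The thapsigargin comparisons ask the same of cells under ER stress. After 1 h immediate early genes had risen. Nr4a1 rose from 21.5 ± 3.55 to 135 ± 23.7 CPM (SD, n = 4 each), a log2 fold change of 2.66 ± 0.15 (SE; adjusted p = 6.80e-15). Fosb rose by 3.99 ± 0.33, and Fos and Egr1 by 1.91 ± 0.10 and 1.94 ± 0.33. The stress factor Ddit3 (ENSMUSG00000025408.15), which encodes CHOP, rose from 5.64 ± 0.271 to 32.6 ± 9.33 CPM (SD, n = 4 each), a log2 fold change of 2.53 ± 0.15 (SE; adjusted p = 1.08e-14). Atf3 rose by 2.23 ± 0.33 and Atf4 by 1.11 ± 0.12. The ER chaperone gene Hspa5 (ENSMUSG00000026864.13) had gone from 542 ± 26.6 to 862 ± 98.3 CPM, and Gdnf, a neurotrophic factor gene, had risen by 1.98 ± 0.35.

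Immediate early genes rose in 17 of 23 (18 adjusted over the list alone, camera adjusted p = 2.25e-21). Chaperone and ER-associated degradation genes rose in 13 and fell in 2 of 33 (16 and 2 adjusted over the list alone, camera adjusted p = 1.50e-07, adjusted p = 0.323 with an estimated correlation), with Derl3 (1.81 ± 0.34), Herpud1 (1.12 ± 0.12), Xbp1 (0.87 ± 0.08) and Dnajb9 (0.82 ± 0.12). Integrated stress response genes rose in 7 and fell in 1 of 35 (7 and 3 adjusted over the list alone), with Chac1 (1.61 ± 0.34) and Ppp1r15a (0.52 ± 0.09). Trib3 stood at 1.89 ± 0.354 against 2.18 ± 0.165 CPM and did not pass. Cholesterol biosynthesis genes rose in 10 of 24 (12 adjusted over the list alone, camera adjusted p = 2.30e-06, adjusted p = 0.758 with an estimated correlation), with Hsd17b7 (1.13 ± 0.25) and Stard4 (1.11 ± 0.17). The 20S proteasome genes fell in 8 of 14 (13 adjusted over the list alone, camera adjusted p = 2.34e-09, adjusted p = 0.323 with an estimated correlation), with Psmb3 (-0.37 ± 0.08) and Psma7 (-0.34 ± 0.07). The ribosomal protein list had a median log2 fold change of -0.21 (camera adjusted p = 4.59e-06, adjusted p = 0.758 with an estimated correlation). The NRF2 list had a median of -0.15 (camera adjusted p = 0.0288, adjusted p = 0.374 with an estimated correlation). Among other genes, Mir17hg (-1.13 ± 0.08) fell, and of the interferon genes Mx2 (1.23 ± 0.20) rose. The GTPase and MHC class I lists had median log2 fold changes of -0.43 (camera adjusted p = 0.576) and -0.07 (camera adjusted p = 0.191). The myelin list had a median of 0.23 (camera adjusted p = 0.764) and the proliferation list of -0.18 (camera adjusted p = 0.191).

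At 1 h 1331 genes differed (1001 higher, 330 lower; edgeR quasi-likelihood test), 79 by at least 2-fold. Without untreated 1 h replicate 3 or thapsigargin 1 h replicate 4, cholesterol genes rose in 6 and proteasome genes fell in 5 and 3. The count falls to 808 without thapsigargin 1 h replicate 4, to 805 with no filter on low counts and to 179 and 832 within the lower and upper 20 library numbers. With the isoform table the share higher is 95.6%, against 75.2%.

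At 8 h of thapsigargin ER stress genes were among the largest rises. Hspa5 rose from 626 ± 46.01 to 9715 ± 404 CPM (SD, n = 4 each), a log2 fold change of 3.96 ± 0.07 (SE; adjusted p = 1.49e-30). Ddit3 rose from 6.47 ± 1.05 to 559 ± 27.3 CPM (SD, n = 4 each), a log2 fold change of 6.42 ± 0.16 (SE; adjusted p = 3.16e-27). Trib3 (ENSMUSG00000032715.9), a pseudokinase induced by CHOP, went from 0.92 ± 0.196 to 372 ± 17.8 CPM. The stress genes Nupr1 and Chac1 rose 1203-fold and 169-fold, the cystine transporter gene Slc7a11 483-fold and the BH3-only apoptosis gene Hrk 75.1-fold. DNA replication genes were among the largest falls, Tk1 by 16.1-fold, Mcm3 by 14.2-fold and Chaf1b by 16.9-fold. Pdgfra fell from 2648 ± 48.8 to 1012 ± 55.6 CPM (SD, n = 4 each), a log2 fold change of -1.39 ± 0.17 (SE; adjusted p = 1.71e-08).

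All 35 integrated stress response genes (camera adjusted p = 4.23e-29) and all 33 chaperone and ER-associated degradation genes (camera adjusted p = 3.15e-36) rose. Among them were Ppp1r15a (4.37 ± 0.10), Atf4 (2.56 ± 0.12), Derl3 (8.82 ± 0.25), Creld2 (4.89 ± 0.11) and Dnajb9 (3.82 ± 0.13). Proliferation genes fell in 24 of 25 (camera adjusted p = 2.67e-09, adjusted p = 0.64 with an estimated correlation). Cholesterol biosynthesis genes fell in 18 of 24 (camera adjusted p = 3.79e-05, adjusted p = 0.798 with an estimated correlation), with Acat2 (-2.64 ± 0.15), Nsdhl (-2.24 ± 0.17) and Dhcr7 (-2.01 ± 0.12). Premyelinating genes fell in 9 of 13 (camera adjusted p = 0.0263, adjusted p = 0.798 with an estimated correlation), with Kif19a (-3.59 ± 0.68) and Gpr17 (-1.98 ± 0.36). Lineage transcription factors rose in 2 and fell in 6 of 9, with Olig1 (-1.95 ± 0.18) and Sox8 (-1.62 ± 0.22) against Zfp536 (2.06 ± 0.21). Progenitor genes rose in 3 and fell in 12 of 18. Myelin genes fell in 8 of 23, with Gjb1 (-2.29 ± 0.21) and Ugt8a (-2.04 ± 0.33). The 20S proteasome fell in 11 of 14 (camera adjusted p = 0.00429, adjusted p = 0.798 with an estimated correlation). Heat shock genes fell in 5 of 10 (camera adjusted p = 0.0263, adjusted p = 0.57 with an estimated correlation), with Hspa8 (-2.06 ± 0.08) and Dnajb1 (-0.96 ± 0.08). Apoptosis genes rose in 2 and fell in 11 of 21, with Casp6 (-1.48 ± 0.15). Several genes that IFN-gamma raised fell here: Irgm1 (-2.53 ± 0.18), Tap1 (-1.87 ± 0.17) and Irf1 (-1.13 ± 0.12). The signalling list rose in 1 and fell in 7 of 17 (1 and 5 adjusted over the list alone). The GTPase list rose in 3 and fell in 1 of 19 (1 and 1 adjusted over the list alone). The immediate early list rose in 7 and fell in 6 of 23, with Nr4a2 (2.11 ± 0.21) against Egr2 (-3.52 ± 0.36) and Egr1 (-2.84 ± 0.40). The NRF2 list rose in 5 and fell in 4 of 11, with Hmox1 (1.85 ± 0.11) and Sqstm1 (1.49 ± 0.10) against Prdx1 (-1.32 ± 0.09). Neuron markers rose in 5 and fell in 3 of 9, with Gad1 (5.53 ± 0.40), Snap25 (2.09 ± 0.14) and Reln (1.89 ± 0.32). Astrocyte markers fell in 3 of 10, with Aldoc (-1.76 ± 0.10).

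At 8 h 9174 of the 15135 genes differed (4482 higher, 4692 lower; edgeR quasi-likelihood test), 2960 of them by at least 2-fold. Signalling genes fell in 4 without untreated 8 h replicate 4 or thapsigargin 8 h replicate 3. The effect at 8 h differed from that at 1 h for 7181 genes (3429 upward, 3752 downward). These included 35 of 35 integrated stress response and 33 of 33 chaperone genes upward, and 14 of 23 immediate early, 21 of 24 cholesterol and 24 of 25 proliferation genes downward, while 3 immediate early genes moved upward.

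**Figure D4:**
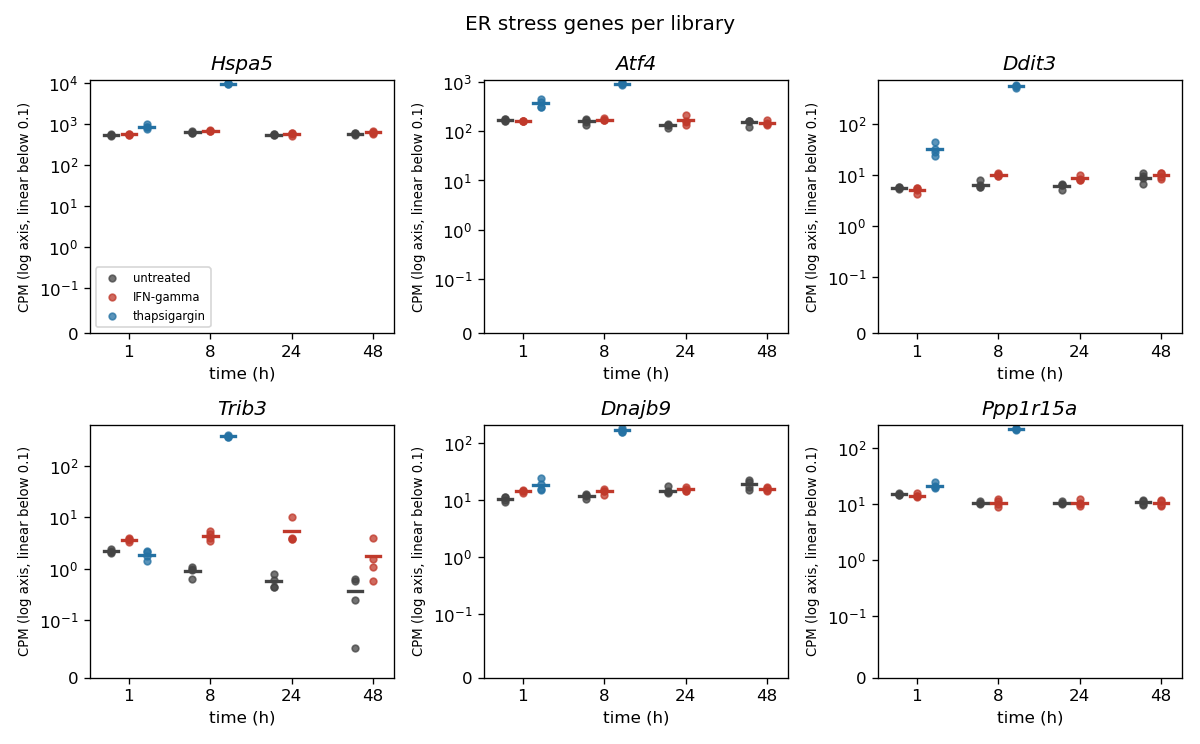
CPM of Hspa5, Atf4, Ddit3, Trib3, Dnajb9 and Ppp1r15a (y axes, logarithmic above 0.1 and linear below) by time in h (x axes), 1 point per library and a bar at the mean of 4 libraries, for untreated, IFN-gamma and thapsigargin cells. The thapsigargin libraries of 8 h stand apart in each panel, with Hspa5 at a mean of 9715 CPM against 626 CPM in untreated cells.

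Set directly against each other, the treatments differed at 8 h along both programmes. The log2 difference, IFN-gamma minus thapsigargin, was 8.78 ± 0.25 for Psmb8 and -3.85 ± 0.07 for Hspa5. Under IFN-gamma, 19 of 19 GTPases, 19 of 20 MHC class I genes, 24 of 25 proliferation genes and 18 of 24 cholesterol genes were higher. By contrast 34 of 35 integrated stress response genes and 33 of 33 chaperone genes were lower, and 1 integrated stress response gene was higher. At 1 h 16 of 23 immediate early genes and 11 of 24 cholesterol genes were lower under IFN-gamma, and 2 immediate early genes and 12 of 19 GTPases higher, with Irf1 at 4.25 ± 0.13 and Fos at -1.70 ± 0.10. Between them 921 genes differed at 1 h (261 higher under IFN-gamma, 660 lower) and 9289 at 8 h (4761 and 4528; edgeR quasi-likelihood test). In the lower 20 library numbers alone 193 genes passed at 1 h. Without thapsigargin 1 h replicate 1, cholesterol genes were lower in 7, and without thapsigargin 1 h replicate 4 or IFN-gamma 1 h replicate 1 or 4 in 6.

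Some genes moved the same way under both treatments. At 8 h 791 genes were higher and 987 lower under each, where independent lists of these lengths would share 585 and 569. Another 471 were higher under IFN-gamma and lower under thapsigargin and 398 the reverse. Progenitor genes such as Pdgfra and C1ql1 and the premyelinating genes Gpr17 and Kif19a were lower under both. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.159 and a covariance of 0.178. Both comparisons use the same untreated libraries. Simulated groups with no change against those controls gave a correlation of 0.511, a covariance of 0.014 and 0 shared calls. With no gene changed hardly any calls could arise, so the 0 does not measure how shared controls affect the overlap of called genes. With the untreated libraries split, 2 for each treatment, the correlation was 0.133 and the covariance 0.159, with 804.5 and 816.5 shared genes on average over 6 splits. At 1 h 36 genes were higher and 7 lower under both, against 10.8 and 0.698 for independent lists. With the controls split the shared genes came to 9 and 0.167 on average, against 3.24 and 0.0873, and the correlation went from 0.188 to -0.0456. The covariance was 0.0239, against 0.0179 in simulated groups and -0.00843 with the controls split. The correlation at 1 h is thus not shown to be more than an effect of the shared controls. The split fits have fewer controls per treatment and also call fewer genes.

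**Figure D5:**
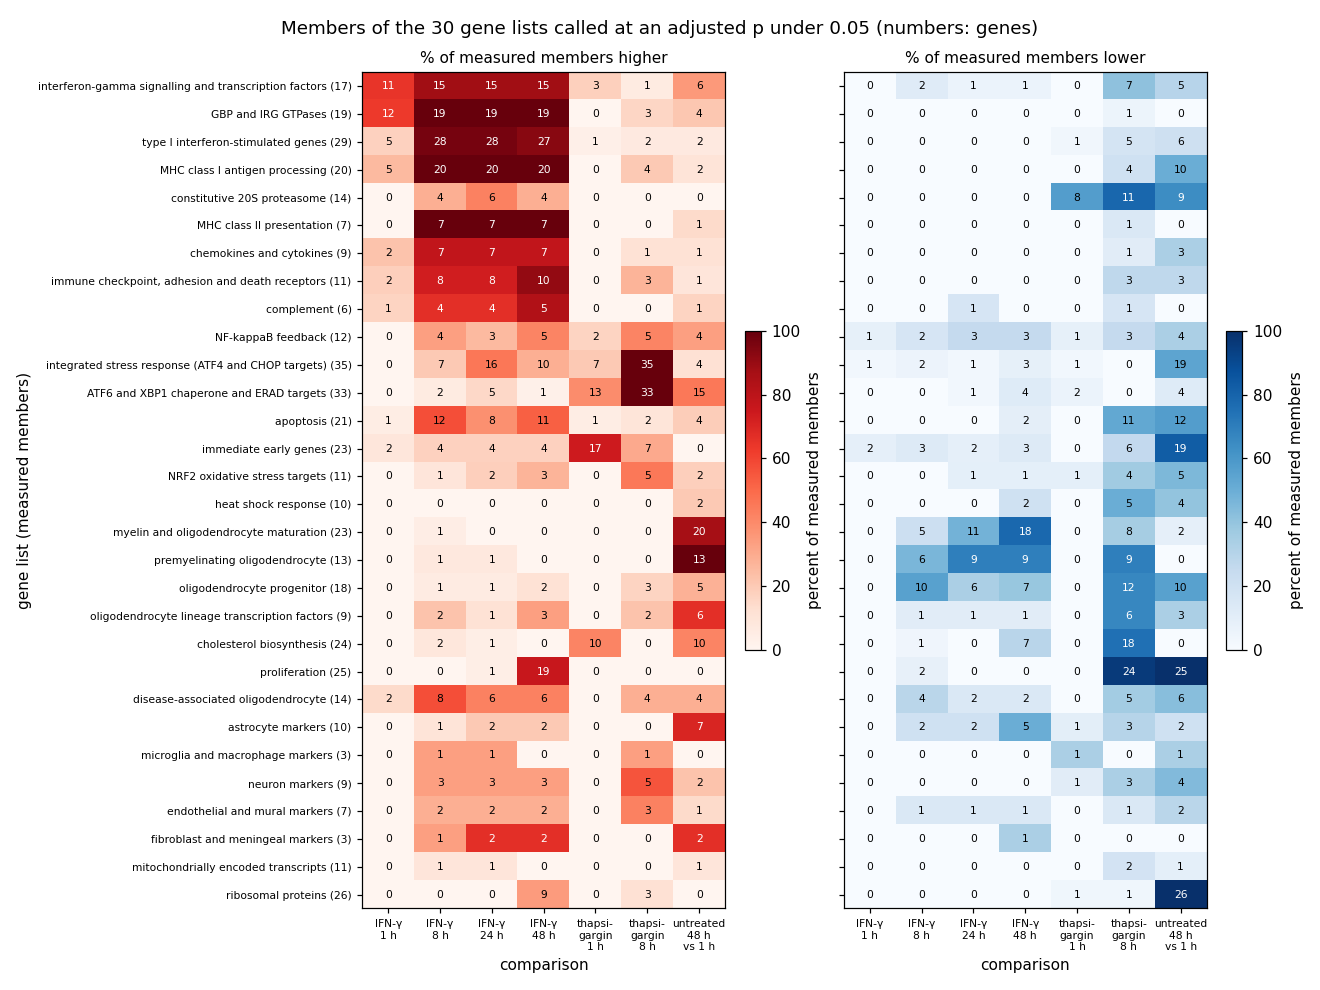
Percent of the measured members of each of 30 gene lists (rows, with the number measured) that were higher (left) or lower (right) at an adjusted p under 0.05 in 7 comparisons (columns), with the number of genes in each cell. IFN-gamma raises all 20 MHC class I and all 19 GTPase genes from 8 h on, thapsigargin at 8 h raises all 35 integrated stress response and all 33 chaperone genes, and 18 of 23 myelin genes are lower at 48 h of IFN-gamma.

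Some values carry a limit from how reads were counted. Reads of near-identical copies, such as Tgtp1 and Tgtp2, the H2 genes, the guanylate-binding and Serpina3 families, could be shared between them. Overlapping or antisense genes cannot be told apart where the use of strand is not given, so single members of those families are less certain than their lists.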

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

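The tests of whether IFN-gamma lowers Y-linked transcripts, of whether the libraries hold cells of different sex, of reads lost to ribosomal-RNA-like features and of other cell types were chosen after the result was seen, and the refits with a Y-linked covariate or without ribosomal-RNA-like features were added after seeing the data. The first results listed are single libraries far from the others of their group, by Dixon's test with a critical value of 0.829. It marked 31 of 246 groups of 4 values, where about 1 in 20, or 12.3, come up by chance. That rate does not hold for genes of few reads. A library with any reads is always marked when the others of its group have none. The Cd74 mark in thapsigargin 1 h rests on 1 read. Values are CPM unless a unit is given, followed by the range of the other 3 libraries.

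Of the untreated libraries, replicate 4 of 24 h was higher in Mbp (325 against 89.8 to 120.4), Myrf (134 against 89.2 to 96.2) and Ciita (0.636 against 0 to 0.0543) and lower in Pdgfra (1674 against 2437 to 2499) and Atf4 (118 against 136 to 139.7). Replicate 2 of 48 h was lower in Mog (5.02 against 23.7 to 26.3) and Atf4 (123 against 162 to 166) and had Cd74 at 0.0905 against 0. At 8 h replicate 4 was higher in Mbp (86.1 against 39.97 to 47.4), replicate 1 lower in Gbp2 (0.0501 against 0.133 to 0.147) and replicate 3 higher in Irf1 (26.4 against 23.8 to 24.1). Replicate 4 of 48 h was lower in Gbp2 (0.216 against 0.362 to 0.369).

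Of the IFN-gamma libraries, replicate 3 of 1 h was higher in B2m (39.5 against 23.05 to 25.8), Psmb8 (3.71 against 1.61 to 1.81) and Ciita (0.777 against 0 to 0.1005), replicate 2 in Ppp1r15a (15.8 against 13.6 to 13.8) and replicate 1 in Pdgfra (2536 against 2399.6 to 2401). At 24 h replicate 1 was higher in Trib3 (10.3 against 3.70 to 3.94) and Ddit3 (10.1 against 8.01 to 8.33) and replicate 2 lower in Irf1 (789 against 879.9 to 886). Socs1 was higher in replicate 1 of 48 h (83.7 against 37.3 to 42.8), and thapsigargin 1 h replicate 3 had Cd74 at 0.0535 against 0. The depth of IFN-gamma 8 h replicate 4 was 15.7 M reads against 18.3 to 18.7. Ribosomal-RNA-like features took 3.58% against 0.591 to 1.02% of the reads of IFN-gamma 48 h replicate 1, and satellite-like features 1.69% against 3.55e-04 to 0.0123% in IFN-gamma 1 h replicate 3, 0.513% against 0.029 to 0.0906% in 24 h replicate 4 and 1.82% against 5.71e-05 to 0.273% in 48 h replicate 2. The satellite-like share was 0.863% against 5.89e-05 to 0.11% in thapsigargin 1 h replicate 4 and 3.42% against 3.41e-04 to 0.146% in untreated 24 h replicate 4. Untreated 24 h replicate 4, IFN-gamma 1 h replicate 3 and IFN-gamma 48 h replicate 2 also had reads on 31854, 30113 and 29190 genes, more than any other library. The high Ciita values, under 1 CPM, came from the first 2 of these. The cause was not tested.

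IFN-gamma 1 h replicate 2 had 28.3% against 0.696 to 3.58% of its reads on ribosomal-RNA-like features and a TMM factor of 0.748 against 1.01 to 1.04, and its median log2 rise of the 167 genes called higher without it was 0.869, against 1.01 to 1.16 in the other 3, each on the genes called without it. An untreated library in its place is argued against, since the untreated libraries lie between -0.06 and 0.02. With the 7 ribosomal-RNA-like or repeat-derived features taken out the rise was 0.868, against 1.00 to 1.16. The rise was thus almost unchanged and stayed below the others, by less than their own range. The TMM factor had already scaled for these reads, so taking them out could change little. The test therefore does not decide whether reads lost to these features play a part. No biological explanation was tested.

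Y-linked transcripts were nearly absent from 8 of 16 IFN-gamma libraries and present in every untreated one. An effect of IFN-gamma on these transcripts is argued against, because 8 of the 16 IFN-gamma libraries lay at or above the lowest untreated library (103 CPM). Xist was at least 319.5 CPM in the low libraries and at most 11.1 CPM in the other IFN-gamma libraries, which is consistent with libraries from cells of different sex. With the Y-linked level as a covariate 95.9% of the genes called at 8 h of IFN-gamma were called in the same direction. That argues against the sex of the cells as the account of most of them. No untreated library had a Y-linked level as low as the 8 low IFN-gamma libraries. The covariate therefore cannot separate other differences between cell preparations from the treatment in those libraries. The labels do not give the sex of the pups, and some untreated libraries held both Y-linked transcripts and Xist (up to 183 CPM).

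Myelin genes were lower after 48 h of IFN-gamma than in untreated cells. The sex of the cells as the cause is argued against, since 17 of the 18 myelin genes were still lower with the Y-linked covariate. Of 32 measured markers of 5 other cell types 7 were called lower, in 3 lists, and 9 higher. A larger share of all 5 types at once is argued against mainly by the astrocyte list, where 5 of 10 were lower and 2 higher. The endothelial and the fibroblast list each had 1 marker lower and 2 higher. A larger share of a type whose markers rose therefore stays open. Maturation that was held back stays open too: of 1747 genes outside the lists called both in untreated cells from 1 to 24 h and at 48 h of IFN-gamma, 1416, or 81.1%, moved in opposite directions. A loss of the more mature cells from the culture would give the same directions, which was not tested.

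Treatment effects that differed between times were found by a test of the interaction: 1874 genes for IFN-gamma between 8 and 1 h, 2577 between 48 and 8 h, and 7181 for thapsigargin between 8 and 1 h. Each was refitted on its own groups alone and set against other splits of treated and untreated libraries within each time, 100 drawn for each. For thapsigargin the real grouping gave 7881 genes and the highest other split 214, and 1 split, the real one, gave as many. For IFN-gamma 3 and 3 splits, the real one included, gave as many, the real groupings 2717 and 917 genes and the highest others 3997 and 2145. Such splits break up the treatment effect itself, and one that keeps the libraries of 1 time in their groups carries that effect into the interaction. They therefore do not show whether chance can be excluded for any of the 3 interactions.

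For each comparison of 2 groups, fitted on its own libraries alone, 1 of the 35 splits, the real one, gave as many genes. An arbitrary grouping of these libraries is therefore argued against, though no share below 1 in 35 can be reached. Splits that mix the 2 groups add their difference to the spread, and no split tests differences between cultures or preparations. The real count and the highest of the other splits were 217 and 22 for IFN-gamma at 1 h, 4299 and 1 for IFN-gamma at 8 h, 2988 and 0 for 24 h and 2041 and 0 for 48 h. They were 1918 and 47 for thapsigargin at 1 h, 9148 and 0 for thapsigargin at 8 h, 707 and 21 for IFN-gamma against thapsigargin at 1 h and 9650 and 0 for the same at 8 h. Last, they were 1913 and 10 for untreated cells from 1 to 8 h, 4688 and 1 for 1 to 24 h and 8439 and 0 for 1 to 48 h.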

How the results depend on the processing

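The refits with the Y-linked covariate and without 7 ribosomal-RNA-like or repeat features were the alternatives chosen after the result was seen. Of the counts of genes under all alternatives, 249 lay within 1.5 times the count reported and 27 did not. RLE size factors, DESeq2, the block on library numbers and both added refits were among the settings that left every count within it. Leaving out each library in turn gave, beside the reported counts and as lowest to highest, 195 for IFN-gamma 1 h (147 to 204), 3811 for IFN-gamma 8 h (3186 to 3576), 3493 for IFN-gamma 24 h (2683 to 3412) and 5570 for IFN-gamma 48 h (4135 to 6441). For thapsigargin and the direct comparison it gave 1331 for thapsigargin 1 h (808 to 1366), 9174 for thapsigargin 8 h (8706 to 8940), 921 for IFN-gamma against thapsigargin 1 h (667 to 867) and 9289 for IFN-gamma against thapsigargin 8 h (8872 to 8983). For untreated cells it gave 1049 for untreated 8 h (538 to 1108), 4282 for untreated 24 h (2314 to 4187) and 9436 for untreated 48 h (8884 to 9711), and for interactions 1874 for IFN-gamma effect between 8 and 1 h (1584 to 1784), 2577 for IFN-gamma effect between 48 and 8 h (1689 to 4297) and 7181 for thapsigargin effect between 8 and 1 h (6810 to 7021). The lowest for thapsigargin 1 h came without its replicate 4, for untreated 8 and 24 h without replicate 4 of that time, and for the IFN-gamma effect between 48 and 8 h without untreated 48 h replicate 3. The highest for that effect came without untreated 48 h replicate 2. Without untreated 1 h replicates 1 and 2 untreated 8 h gave 588 and 615. Within the lower 20 library numbers, which leave 2 libraries a group, the counts outside 1.5 times were 80 for IFN-gamma 1 h, 1526 for IFN-gamma 24 h, 3039 for IFN-gamma 48 h, 179 for thapsigargin 1 h, 193 for IFN-gamma against thapsigargin 1 h, 125 for untreated 8 h, 430 for untreated 24 h, 839 for IFN-gamma effect between 8 and 1 h and 86 for IFN-gamma effect between 48 and 8 h. Within the upper 20 they were 2456 for IFN-gamma 8 h, 832 for thapsigargin 1 h, 182 for untreated 8 h and 1031 for IFN-gamma effect between 8 and 1 h. With no filter, which tests more genes, they were 805 for thapsigargin 1 h and 611 for untreated 8 h. With only the groups compared they were 2041 for IFN-gamma 48 h, 1913 for untreated 8 h and 917 for IFN-gamma effect between 48 and 8 h, and with the isoform table summed per gene 2497 for untreated 24 h and 1490 for IFN-gamma effect between 48 and 8 h. For these settings the cause was not tested. Of the values of named genes 11091 kept direction and side of the threshold, 740 kept the direction only, 48 came to pass it and 3 reversed. Reversed were Arc at 48 h of IFN-gamma in the lower 20 library numbers (log2 fold change 0.24), and Rpl5 (-0.0891) and Acta2 (0.00729) at 8 h of thapsigargin with the isoform table, and the cause was not tested. Of 270 tests of gene lists 89 were called by camera. Of these 38 were called with an estimated correlation, 88 with the block and 78 by fry in the same direction. No paired analysis was run, because the labels name no pairing and the replicate numbers follow the order of deposition. A pairing read from the levels of the Y-linked genes and Xist was not tried. The planned share of spliced Xbp1 was not run, since none of the 4 reference transcripts lacks the 26-base intron. Depth limits genes of few reads. Changes of under 2-fold are limited too. Simulated counts for IFN-gamma at 1 h, changed only in genes above a floor of expected reads, gave back 70.1% at 1.5-fold.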

Other observations

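No test in this part was chosen after the result was seen. At 8 h of thapsigargin further genes changed. The hormone gene Fgf21 (6.06 ± 2.24 CPM against 0.0125 ± 0.025 in untreated cells) and Trim66 (9.17 ± 0.28) and Sec24d (5.06 ± 0.11), the last a coat subunit of vesicles leaving the ER, rose, and Tcf19 (-3.74 ± 0.26), Slfn9 (-4.10 ± 0.25) and Steap3 (-3.18 ± 0.46) fell. Some immune genes rose without IFN-gamma, among them Ddx60 (3.18 ± 0.37), H2-M3 (2.87 ± 0.22), Usp18 (2.30 ± 0.66) and Gbp3 (1.65 ± 0.20) and the fractalkine gene Cx3cl1 (1.08 ± 0.21), while Serpina3n (-1.58 ± 0.19), H2-Ab1 (-1.16 ± 0.27) and Cish (-0.41 ± 0.15) fell. The MHC class I list rose in 4 and fell in 4 of 20 (3 and 4 adjusted over the list alone) and type I interferon-stimulated genes rose in 2 and fell in 5 of 29 (2 and 3 adjusted over the list alone) by edgeR's quasi-likelihood test, the latter falling in 3 without untreated 8 h replicate 2 or thapsigargin 8 h replicate 3. Ribosomal protein genes rose in 3 and fell in 1 of 26 (2 and 1 adjusted over the list alone), with Rpl4 (0.34 ± 0.08), Rps6 (0.24 ± 0.10) and Rpl5 (0.22 ± 0.07) against Rpl11 (-0.53 ± 0.09), though Rpl5 reversed with the isoform table, and mitochondrially encoded transcripts fell in 2 of 11, with mt-Nd1 (-0.39 ± 0.11) and mt-Nd3 (-0.98 ± 0.22).

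Under IFN-gamma the AP-1 gene Jun was higher at 8, 24 and 48 h, by 2.33 ± 0.17, 2.60 ± 0.17 and 2.97 ± 0.18 on the log2 scale, and Il18bp, which encodes an inhibitor of interleukin 18, by 2.84 ± 0.11, 3.23 ± 0.11 and 3.45 ± 0.11. The glutamate transporter gene Slc1a3 was higher at 8 and 24 h (1.03 ± 0.15 and 0.84 ± 0.15), the receptor gene Kdr lower at 8, 24 and 48 h (-0.88 ± 0.20, -1.36 ± 0.21 and -1.60 ± 0.23), and the matrix gene Tnr lower at 24 and 48 h (-1.07 ± 0.20 and -0.80 ± 0.19). Constitutive proteasome genes rose in 4 of 14 at 8 h, with Psmb4 (0.35 ± 0.12), Psma2 (0.32 ± 0.08) and Psma3 (0.26 ± 0.05). In untreated cells between 1 and 48 h the neuropeptide precursor gene Vgf (-4.72 ± 0.71), the retinaldehyde dehydrogenase gene Aldh1a3 (-3.39 ± 0.49) and the tubulin gene Tubb6 (-3.56 ± 0.40) fell, all by edgeR's quasi-likelihood test with adjusted p under 0.05.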
